A study of Mus musculus with 18 samples.

How the data were processed

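Polyadenylated RNA from mouse liver was sequenced from stranded libraries (TruSeq Stranded mRNA, total RNA by RNeasy) in 18 samples, 3 pooled libraries in each of 6 groups of genotype and diet. Per the submitters' processing notes, bcl2fastq 2.17, Trimmomatic 0.30, TopHat2 2.0.8 and Picard 1.84 were used with the mm10 build. The deposited files hold a read count per gene locus and library, per the file headers, and these counts were used as they stood. The counting tool, its strand setting and its handling of overlapping loci are not given in the sources used here. The files held 52463 loci, of which 31099 carried a gene identifier and were analysed, and 21364 did not. A total of 12 blank or total rows in 6 files were left out, and 5 read columns that match no sample were not used. In 28 cases a symbol altered by a spreadsheet was repaired through its identifier, and all 474 list members were found. Of the loci with an identifier 11422 had 0 counts in all libraries, and this held for 95.1% of loci that lie inside another locus against 26.1% of the rest, so genes at 0 inside another locus were taken as not measured. Of the lists and the fixed set 27 genes had 0 counts in all libraries, and 23 of these lay inside another locus, Txnip, Acaa1a, Fabp4, Nqo1 and Lipe included.

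Depth was 68.9 to 151 M counts per library, or 31.8 to 44.5 M without the Mup loci. On simulated data with known changes, 66.7% to 73.8% of 2-fold and 35.9% to 44.6% of 1.5-fold changes were recovered in comparisons of 3 against 3, and 3.20% to 6.47% of calls were false. Camera called 0 of 50 random lists of 25 genes on simulated data. Genes were drawn independently there, so this does not test camera on lists of correlated genes. With as few genes changed as in these simulations, differences of less than about 2-fold were therefore often missed. Recovery can differ where many genes change. Of 5583 genes called with Wy in WT, only 899 rises and 844 falls reached 2-fold.

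Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 6 groups, scaled by TMM, and fitted in 1 quasi-likelihood model of 18 libraries with a coefficient per group, no block and 12 residual degrees of freedom, at a common biological coefficient of variation of 0.140. The F-test was used, with Benjamini-Hochberg adjustment over 14241 genes and a threshold of 0.05. CPM were taken on the TMM effective library size. Fold changes are those fitted with a prior count of 0.125, and the SE is the fold change over the square root of F. A gene with 0 counts in a group was given as a bound from 3 counts over that group. Every p printed beside a gene or a list is an adjusted p of these edgeR fits or of camera. With 3 against 3 libraries the smallest permutation p is 0.1, so p-values of single genes rest on the fitted spread between pools.

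The 9 comparisons were each diet against control in each genotype, KO control against WT control, the 2 interactions of genotype and diet, and Wy against fenofibrate in each genotype. Comparisons in a genotype shared their 3 control libraries. The overlap of both diets was therefore set against 20 simulations of unchanged groups on the same controls, as 3 controls cannot be split. The genotype effect was set against Wy in 20 simulations that kept the fitted Wy effects of called genes and shuffled the genotype effects among genes of like abundance in 50 bins, a test chosen after the result was seen. The groups, comparisons, lists and most alternatives were fixed before the data were examined.

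Gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over 32 lists within a comparison, and with a correlation estimated per list and with fry as alternatives. The 23 pathway lists covered peroxisomal, mitochondrial and omega oxidation, ketogenesis, lipid handling, lipogenesis, cholesterol synthesis, bile acids, lipoproteins, the acute phase, xenobiotic metabolism, NRF2, the cell cycle, amino acids and urea, glucose, nuclear receptors, hepatokines, circadian genes, stress, male-biased, female-biased, pericentral and periportal genes. The 9 cell type lists covered Kupffer cells, infiltrating myeloid cells, lymphocytes, stellate cells, endothelium, cholangiocytes, erythroid cells, adipose tissue and pancreas. Beside each list stand the counts of members called over all genes, and where they differ those adjusted over the list alone.

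Genes were named by a rule. For the 5 comparisons with a control group it took the 10 largest rises and the 10 largest falls among called genes whose 6 libraries did not overlap and whose higher group averaged at least 5 CPM, leaving out predicted gene models and numbered pseudogenes. For the 4 other tests it took 5 each way, without the overlap condition for interactions. It added 33 fixed genes and up to 4 members per list with the smallest p. From these the text names a part, with preference for genes that kept their call without any library, a preference applied after the values were seen. Results of some genes are not reported here.

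Alternatives were RLE scaling, library totals, no filter, a filter of 5 CPM in 3 libraries, limma-voom, DESeq2 1.42.0, a block on the library number, a fit of the compared groups alone, an adjusted p of 0.01, a test against 1.5-fold, and leaving out each library. Chosen after seeing the data were robust dispersion, the Mup loci left out, all loci included, lists without each library and list medians under other scalings. Robust dispersion was at first used by mistake in place of the planned edgeR default, and its counts were seen before the default was restored. A pseudocount alternative does not apply to counts tested by a count model. Intervals of shares are exact binomial and cover counting error only.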

Results

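Liver RNA was profiled from wild type (WT, Ppara+/+) and Ppara-null (KO, Ppara-/-) mice at 8 weeks of age, fed a control diet, a diet with 0.1% Wy14,643 (Wy) or a diet with 0.5% fenofibrate for 48 h. Each of the 6 groups held 3 libraries, and each library was a pool of 3 to 5 livers. The SE and p-values of single genes therefore rest on the spread between pools, fitted over all 6 groups. Camera p-values of lists compare members with other genes at a preset correlation, so they do not measure that spread alone. Total counts per library were 68.9 to 151 M over 31099 loci with a gene identifier, and 14241 genes were tested. The 25 loci of the major urinary protein (Mup) family took 71.4 ± 2.16% of all counts in WT control and 52.7 ± 3.00% in WT Wy (SD, n = 3 each). The share was 54.0 ± 5.20% in WT fenofibrate, 62.2 ± 2.71% in KO control, 72.2 ± 4.02% in KO Wy and 64.6 ± 4.15% in KO fenofibrate (SD, n = 3 each). The first principal component of the 1000 most variable genes held 77.0% of the variance and the second held 7.21%, and libraries of the same group correlated with r of 0.981 to 0.992. All changes are given relative to the median gene. Scaling by library totals instead moved the median gene by 0.79 log2 units in WT Wy against control, 0.82 in WT fenofibrate, -0.33 in KO Wy, 0.05 in KO fenofibrate and 0.32 in KO control against WT control.

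Ppara itself (gene 19013, mm10 chromosome 15, 85735564 to 85806851) was counted in every library, at 5214 to 9045 counts in each of the 9 WT libraries and 1134 to 2328 in each of the 9 KO libraries. It stood at 59.0 ± 7.88 CPM in WT control, 70.7 ± 1.54 in WT Wy and 74.4 ± 14.8 in WT fenofibrate, against 15.2 ± 2.61 in KO control, 15.4 ± 2.09 in KO Wy and 15.1 ± 4.41 in KO fenofibrate (SD, n = 3 each). Ppara was lower in KO control than in WT control by a log2 fold change of -1.96 ± 0.19 (SE, n = 3 against 3, adjusted p = 7.3e-07). Counts left at the locus do not tell whether a working receptor was made. Neither diet moved Ppara past the threshold, with 0.26 ± 0.18 for Wy in WT (adjusted p = 0.27) and 0.33 ± 0.18 for fenofibrate in WT (adjusted p = 0.16).

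The first question was how WT liver responded to Wy. The largest rises included Pdk4, a kinase that restrains pyruvate oxidation, from 0.948 ± 0.0646 to 214 ± 7.04 CPM (SD, n = 3 each, log2 fold change 7.82 ± 0.30, SE, adjusted p = 4.5e-13), and Fbp2, a fructose bisphosphatase of muscle type (8.35 ± 0.30, adjusted p = 2.4e-13). Ehhadh, the bifunctional enzyme of peroxisomal oxidation, rose from 74.0 ± 7.85 to 7829.7 ± 139 CPM (6.73 ± 0.15, adjusted p = 9.0e-16). The fatty acid omega-hydroxylase Cyp4a10 rose by 6.72 ± 0.44 (adjusted p = 7.9e-10). Its close paralogs Cyp4a31 (6.95 ± 0.30) and Cyp4a32 share sequence with it, so the part of each is uncertain. Gm15441, a locus that overlaps Txnip, rose by 5.42 ± 0.12 (adjusted p = 9.0e-16), while Txnip itself held 0 counts in all 18 libraries and was not measured. How reads in this overlap were counted is not known, so every value given for Gm15441 is uncertain. Further rises were called for the lipid droplet protein Plin2 (3.21 ± 0.15), the fatty acid translocase Cd36 (4.69 ± 0.23), the thioesterase Acot1 (6.19 ± 0.19), the pantetheinase Vnn1 (5.14 ± 0.23) and the hormone Fgf21 (2.39 ± 0.27, adjusted p = 6.9e-06). Falls were called for cytochromes P450 of the Cyp2c family, with Cyp2c50 going from 171 ± 28.6 to 3.57 ± 0.241 CPM (-5.58 ± 0.20, adjusted p = 3.0e-13). Cyp2c70 went from 197 ± 19.6 to 4.14 ± 1.01 CPM (-5.57 ± 0.23, adjusted p = 1.2e-12), although these paralogs too share sequence. The acute phase gene Saa1 fell as well (-5.07 ± 1.20, adjusted p = 0.0024). For each of these genes the 3 Wy libraries lay wholly outside the 3 controls, which 10% of unchanged genes would show by chance.

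Most genes of fatty acid oxidation rose with Wy in WT. Of 26 measured peroxisomal genes 19 rose, 4 fell and 3 were not called, the same numbers when adjusted over the list alone, with a median of 1.62 (camera adjusted p = 2.0e-38). Examples were the thiolase Acaa1b (3.81 ± 0.11, SE, n = 3 each) and the peroxisome division gene Pex11a (2.80 ± 0.09). All but 1 of 20 mitochondrial beta-oxidation genes rose and none fell, here and adjusted over the list alone (median 1.79, camera adjusted p = 2.3e-44), among them Hadhb (2.08 ± 0.07) and Cpt1b (3.92 ± 0.12). Of 9 omega-oxidation genes 8 rose and 1 fell in both counts (median 3.48, camera adjusted p = 2.2e-10), with the aldehyde dehydrogenase Aldh3a2 at 3.48 ± 0.11 and Cyp4f14 at -3.38 ± 0.14. All 4 ketogenesis genes rose in both counts (median 1.24, camera adjusted p = 1.8e-05 and adjusted p = 0.064 with an estimated correlation). All 24 genes of fatty acid uptake and storage rose in both counts (median 2.05, camera adjusted p = 2.1e-52), with the transporter Slc27a1 at 5.81 ± 0.17 and the droplet protein Cidec at 6.11 ± 0.18.

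Lipid synthesis and export gave mixed results with Wy in WT. Of 18 lipogenesis genes 9 rose, 3 fell and 6 were not called, alike over the list alone (median 0.62, camera adjusted p = 0.0043 and adjusted p = 0.39 with an estimated correlation, 0.0631 under library totals). The median ran from 0.35 to 0.77 without single libraries, and the call was kept. Elovl5 stood at 1.99 ± 0.11 and Thrsp at -3.28 ± 0.19 (SE, n = 3 each). Cholesterol synthesis was not called (3 of 24 rose, 4 fell, adjusted p = 0.76, median 0.11 and mean 0.04 against a test direction of down). Lipoprotein genes were not called either (2 of 16 rose, 10 fell, adjusted p = 0.29), with Mttp at 1.70 ± 0.08 and Apoc3 at -1.44 ± 0.14. Of 22 bile acid genes 12 fell and 4 rose, or 12 and 5 over the list alone, with a median of -0.58 that became 0.23 under library totals (camera adjusted p = 1.3e-05). The bile acid reductase Akr1d1 stood at -3.63 ± 0.16 and the transporter Slco1a4 at -3.44 ± 0.15.

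Genes of hepatocyte secretion and nitrogen handling were tested next for Wy in WT. Of 25 acute phase genes 16 fell and 1 rose, or 16 and 4 over the list alone (median -1.10, camera adjusted p = 8.6e-05 and adjusted p = 0.38 with an estimated correlation). The complement gene C9 stood at -2.48 ± 0.16 and Itih4 at -2.11 ± 0.15 (SE, n = 3 each). Of 20 amino acid and urea genes 16 fell and 1 rose in both counts, with a median of -0.71 that became 0.10 under library totals (camera adjusted p = 7.8e-12). The glutaminase Gls2 stood at -3.03 ± 0.11 and the urea cycle gene Otc at -2.08 ± 0.10. Of 8 periportal genes 7 fell and none rose in both counts (median -1.42, camera adjusted p = 1.8e-10), such as Ass1 (-2.31 ± 0.12), and 5 of the 8 members were also in other lists. Of 9 pericentral genes 5 fell and 1 rose, or 7 and 1 over the list alone, with a median of -0.77 that became 0.02 under library totals (camera adjusted p = 3.5e-05). Cyp1a2 fell by 2.66 ± 0.13. Xenobiotic genes typical of CAR and PXR fell in 9 of 19 and rose in 5, or 10 and 5 over the list alone, with a median of -0.86 that became -0.06 under library totals (camera adjusted p = 5.4e-09).

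Smaller shifts with Wy in WT depended more on the list test. Of 31 cell cycle genes 16 rose and 1 fell in both counts (median 0.90, camera adjusted p = 0.00025 and adjusted p = 0.43 with an estimated correlation). The median ran from 0.58 to 1.01 without single libraries, and the call was kept. The replication factor Mcm6 stood at 3.60 ± 0.39 and the regulator E2f8 at 2.48 ± 0.13 (SE, n = 3 each). Of 12 male-biased genes 7 fell and 2 rose in both counts (median -1.14, camera adjusted p = 0.0024 and adjusted p = 0.2 with an estimated correlation), with Hsd3b5 at -4.61 ± 0.41. Without WT Wy 3, the library that held Xist counts, the male-biased median was -1.03 (adjusted p = 0.0046). Of 18 NRF2 genes 7 fell and 6 rose in both counts, with a median of -0.19 that became 0.61 under library totals (camera adjusted p = 0.021 and adjusted p = 0.38 with an estimated correlation, 0.0863 under library totals), and the call was lost without WT Wy 3 (adjusted p = 0.0960). Not called were glucose handling (8 of 23 rose, 10 fell, adjusted p = 0.14, median -0.28 and mean 0.57) and hepatokines (5 of 15 rose, 8 fell, adjusted p = 0.29, median -0.39 and mean 0.19). Nor were circadian genes (1 of 14 rose, 7 fell, adjusted p = 0.073) and female-biased genes (4 of 13 rose, 6 fell, adjusted p = 0.11, median 0.11 and mean -0.23). Nuclear receptors (3 of 15 rose, 3 fell, adjusted p = 0.76, median -0.01 and mean 0.03) and stress response genes (2 of 16 rose, 8 fell, adjusted p = 0.2) were not called.

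Markers of other liver cell types were tested in the same way. With Wy in WT, 10 of 11 Kupffer cell markers fell and none rose in both counts, with a median of -0.68 that became 0.13 under library totals (camera adjusted p = 0.0015 and adjusted p = 0.38 with an estimated correlation). Among them the macrophage receptor Csf1r went from -0.68 ± 0.10 (SE, n = 3 each) to 0.13 with that scaling and Clec4f stood at -0.82 ± 0.12. The 2 measured pancreas markers fell (camera adjusted p = 0.04 and adjusted p = 0.18 with an estimated correlation), Cela1 by 1.89 ± 0.20. Of the remaining lists, 0 of 7 myeloid markers (adjusted p = 0.4) and 0 of 4 erythroid markers (adjusted p = 0.5) changed, while 1 of 4 lymphocyte markers (adjusted p = 0.37) and 3 of 8 stellate cell markers (adjusted p = 0.19) fell. In the endothelium list 1 of 9 markers rose and 3 fell (adjusted p = 0.38), and 1 of 5 cholangiocyte markers rose (adjusted p = 0.95). The single measured adipose marker, Cfd, rose by 3.73 ± 0.89 (adjusted p = 0.0053, list adjusted p = 0.33). No cell type marker was a member of any other list.

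In all, 5583 genes were called with Wy in WT, 2875 higher and 2708 lower, of which 899 rose and 844 fell at least 2-fold. A further test against a 1.5-fold change called 1707. Library totals, which take the Mup share into every gene, called 10156, with 9700 higher. Of the 17 lists called, 9 held with an estimated correlation, namely peroxisomal, mitochondrial and omega oxidation, lipid handling, bile acids, xenobiotic, amino acid, pericentral and periportal genes.

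**Figure D1:**
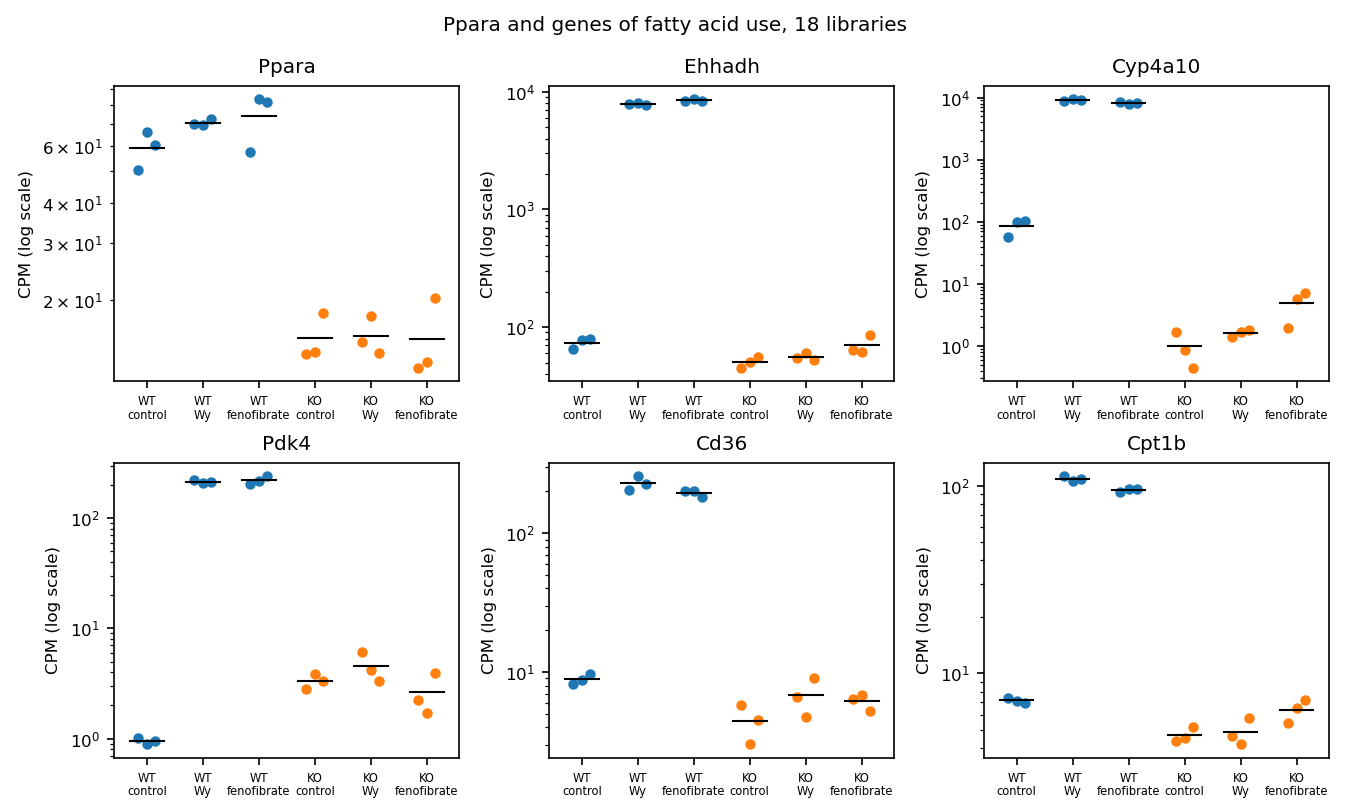
CPM on a log scale in each of 18 libraries for Ppara and 5 genes of fatty acid use in 6 groups, a point per library and a line at the group mean. Ehhadh rose from 74.0 CPM in WT control to 7829.7 with Wy and 8446 with fenofibrate, and was not called in KO.

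**Figure D2:**
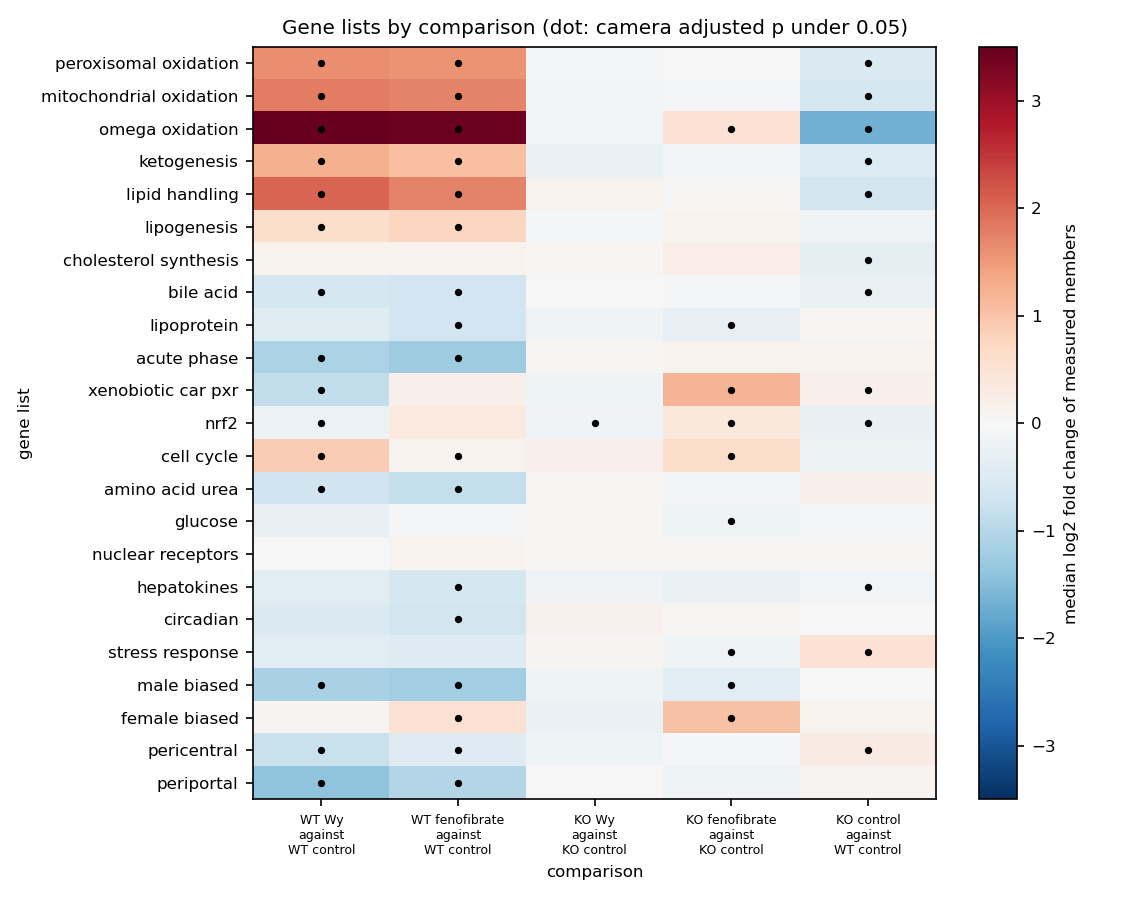
Median log2 fold change of 23 pathway lists in 5 comparisons, with a dot where the camera adjusted p was below 0.05. Mitochondrial oxidation stood at 1.79 and 1.74 in treated WT and at -0.09 and -0.05 in treated KO.

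Fenofibrate was then compared with control diet in WT. Pdk4 rose to 221 ± 19.1 CPM (SD, n = 3, log2 fold change 7.86 ± 0.30, SE, adjusted p = 5.8e-13) and Ehhadh to 8446 ± 142 CPM (6.84 ± 0.15, adjusted p = 7.3e-16). Cyp4a10 rose by 6.58 ± 0.44 (adjusted p = 1.1e-09), Fgf21 by 1.65 ± 0.27, the desaturase Scd1 by 2.42 ± 0.36 and the fatty acid synthase Fasn by 1.18 ± 0.26 (adjusted p = 0.0016). Falls were called for the steroid dehydrogenase Hsd3b5 (-5.32 ± 0.42, adjusted p = 1.2e-08), Cyp2c70 (-5.04 ± 0.22) and the organic anion transporter Slc22a7 (-4.04 ± 0.30). Apoa1, the main HDL protein, fell by 0.84 ± 0.13 (adjusted p = 3.5e-05), a change of -0.03 under library totals.

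Lists of fatty acid use rose with fenofibrate in WT. Peroxisomal genes rose in 20 of 26 and fell in 4 (median 1.56, camera adjusted p = 6.5e-41), with Acaa1b at 3.66 ± 0.11 (SE, n = 3 each). Mitochondrial genes rose in 18 of 20, or 19 over the list alone (median 1.74, adjusted p = 3.3e-40), with Hadhb at 1.90 ± 0.07. Omega-oxidation genes rose in 8 of 9 and fell in 1 (median 3.42, adjusted p = 3.5e-10), and lipid handling genes rose in 22 of 24, or 23 over the list alone (median 1.73, adjusted p = 2.8e-48), with Cidec at 5.61 ± 0.18. Ketogenesis rose in 3 of 4, or 4 over the list alone (adjusted p = 0.00021 and adjusted p = 0.11 with an estimated correlation), with Acat1 at 1.09 ± 0.10. Lipogenesis rose in 10 of 18 and fell in 4 (adjusted p = 0.004 and adjusted p = 0.38 with an estimated correlation). Of 13 female-biased genes 3 rose and 1 fell (median 0.52, adjusted p = 0.00064 and 0.263 under library totals). Among them the thioesterase Acot3 stood at 4.97 ± 0.18 and Hao2 at 3.39 ± 0.46. The median ran from 0.03 to 0.78 without single libraries, and the call was kept. Of the 15 members 4 were also in other lists, Acot3 and Acot4 as peroxisomal and Cyp2b9 and Cyp2b13 as xenobiotic genes. The cell cycle list was barely called (11 of 31 rose, 1 fell, adjusted p = 0.0496 and adjusted p = 0.7 with an estimated correlation, 0.263 under library totals and 0.059 without the Mup loci), with E2f8 at 2.18 ± 0.13. It was lost without WT control 2 or 3, WT Wy 2, WT fenofibrate 1, KO Wy 2 or KO fenofibrate 2 or 3 (adjusted p up to 0.238, without WT fenofibrate 1, where the median was -0.08).

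Secreted and zonal hepatocyte genes were again lower with fenofibrate in WT, some of these lists only relative to the median gene. Acute phase genes fell in 14 of 25 and none rose, or 1 over the list alone (median -1.23, camera adjusted p = 2.8e-07 and adjusted p = 0.26 with an estimated correlation), with C9 at -2.75 ± 0.16 (SE, n = 3 each). Amino acid genes fell in 17 of 20 and rose in 1 (median -0.83, adjusted p = 6.9e-14), and periportal genes fell in 7 of 8 (median -1.03, adjusted p = 1.7e-08), with Cyp2f2 at -1.43 ± 0.12. Male-biased genes fell in 8 of 12 and rose in 2 (median -1.21, adjusted p = 0.00049 and adjusted p = 0.11 with an estimated correlation), with Cyp7b1 at -2.06 ± 0.20. A further group of lists had a median below 0 that turned positive under library totals. These were bile acids (12 of 22 fell, 6 rose, -0.66 to 0.14, adjusted p = 5.4e-05 and adjusted p = 0.06 with an estimated correlation). Lipoproteins did the same (13 of 16 fell, 2 rose, -0.67 to 0.14, adjusted p = 0.0063 and adjusted p = 0.33 with an estimated correlation, 0.0742 under library totals). They also took in circadian genes (7 of 14 fell, or 8 over the list alone, 1 rose, -0.65 to 0.17, adjusted p = 0.015 and adjusted p = 0.38 with an estimated correlation), with Cry1 at -2.11 ± 0.21. Pericentral genes followed (5 of 9 fell, 1 rose, -0.46 to 0.35, adjusted p = 0.00079). Hepatokines did so too (8 of 15 fell, 4 rose, or 6 over the list alone, median -0.62 and mean 0.01, median 0.19 under library totals, adjusted p = 0.028 and adjusted p = 0.38 with an estimated correlation, 0.0806 under library totals), with Ahsg at -1.83 ± 0.10. So did Kupffer markers (10 of 11 fell, -0.64 to 0.17, adjusted p = 0.0032 and adjusted p = 0.38 with an estimated correlation). Hepatokines (adjusted p = 0.0644) and circadian genes (0.0511) were not called without WT fenofibrate 1.

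Xenobiotic genes were not called with fenofibrate in WT (6 of 19 rose, 6 fell, camera adjusted p = 0.081, median 0.17 and mean -0.12). In total 5253 genes were called, 2748 higher and 2505 lower, with 879 rises and 724 falls of at least 2-fold. The test against 1.5-fold called 1532, and library totals called 10396, of which 10002 were higher. Of 18 lists called, 8 held with an estimated correlation, the 4 lists of peroxisomal, mitochondrial and omega oxidation and lipid handling, the amino acid, pericentral and periportal lists, and the female-biased list.

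Both agonist responses in WT were then laid over each other. Of the genes called, 4260 moved the same way with both diets (2276 higher and 1984 lower) and 3 moved in opposite directions, where independent responses would share 555 higher and 476 lower. Across all tested genes, which are not independent replicates, the log2 fold changes correlated with r = 0.915. Both comparisons used the same 3 control libraries, so unchanged groups were simulated against them. These gave r = 0.529 and 0 shared calls on average. The covariance was 0.775 against 0.0477 simulated. Unchanged groups give few calls of any kind, so the 0 does not tell how many of the 4260 the shared controls added. Leaving out single WT libraries gave overlaps of 3584 to 4116, and KO libraries were not left out for this count.

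The direct test asked which genes differed between Wy and fenofibrate in WT. The doses were 0.1% and 0.5% of the diet, so a difference can come from dose as well as compound. Ehhadh (-0.11 ± 0.12, SE, n = 3 each, adjusted p = 0.76, 95% interval -0.36 to 0.14) did not pass the threshold. Nor did Pdk4 (-0.05 ± 0.21, adjusted p = 0.95, -0.49 to 0.40) and Cyp4a10 (0.14 ± 0.34, adjusted p = 0.92, -0.59 to 0.86). Lower with Wy was Cyp2c29, at 112 ± 15.1 against 1658 ± 424 CPM (SD, -3.89 ± 0.19, adjusted p = 1.1e-09). So were the glutathione transferase Gstm3, at 13.2 ± 3.75 against 108 ± 45.4 CPM (-3.04 ± 0.29, adjusted p = 8.2e-06), and the carboxylesterase Ces2a (-1.30 ± 0.10, adjusted p = 1.3e-06). In WT control, Cyp2c29 ranged from 961 to 1368 CPM and Gstm3 from 73.5 to 79.9 CPM. With fenofibrate they ranged from 1169 to 1929 and from 75.8 to 160 CPM, which overlapped the controls. Higher with Wy was the ferritin receptor Scara5 (1.63 ± 0.24, adjusted p = 0.0019). Xenobiotic genes were lower with Wy in 8 of 19, or 11 with 2 higher over the list alone (median -1.21, camera adjusted p = 4.3e-48), and NRF2 genes in 8 of 18, or 11 over the list alone (median -0.44, adjusted p = 4.3e-28), with Gstm1 at -1.10 ± 0.10. Lower with Wy were also 3 of 13 female-biased genes (median -0.99, adjusted p = 2.7e-06), among them Cyp3a41b (-2.54 ± 0.27), and 2 of 8 periportal genes (adjusted p = 0.0019). Without single libraries the female-biased median ran from -1.30 to -0.17, and the call was kept. The female-biased list shares Cyp2b9 and Cyp2b13 with the xenobiotic list. Lipid handling genes were higher as a list (median 0.22, adjusted p = 3.1e-06) with 0 single calls by edgeR and 4 over the list alone. These 5 lists held with an estimated correlation. The xenobiotic median ran from -1.33 to -0.75 without single libraries, and the call was kept.

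A further 7 lists were called between the diets in WT and lost with an estimated correlation, given here with their median and camera adjusted p in this order. Higher with Wy were mitochondrial oxidation (median 0.18, camera adjusted p = 1.9e-05 and adjusted p = 0.27 with an estimated correlation), the cell cycle (0.45, 1.6e-07 and adjusted p = 0.35 with an estimated correlation) and lipoproteins (0.21, 4.6e-06 and adjusted p = 0.13 with an estimated correlation). So were acute phase genes (0.16, 0.0096 and adjusted p = 0.67 with an estimated correlation), glucose handling (0.21, 0.0037 and adjusted p = 0.15 with an estimated correlation) and hepatokines (0.18, 0.0012 and adjusted p = 0.2 with an estimated correlation). The pericentral list was called lower with a median of 0.14 and a mean of -0.35 (adjusted p = 0.026 and adjusted p = 0.17 with an estimated correlation). In all 128 genes were called, 46 higher and 82 lower with Wy, while 1753 had an unadjusted p below 0.05. The number fell to 62, 57 and 40 without WT Wy 1, 2 and 3 and to 72 and 50 without WT fenofibrate 1 and 2, and was 203 without KO fenofibrate 3. DESeq2 called 303, the test against 1.5-fold 18 and library totals 47. The glucose list was lost without WT fenofibrate 1 (adjusted p = 0.0756) and the pericentral list without WT Wy 2 (0.169) or KO fenofibrate 3 (0.0726).

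Next came the response to Wy in KO. Of the fixed genes, Ehhadh stood at 0.15 ± 0.12 (SE, n = 3 each, adjusted p = 0.58). Cyp4a10 stood at 0.67 ± 0.42 (adjusted p = 0.46) and Pdk4 at 0.45 ± 0.23 (adjusted p = 0.38). Insig2, which holds back sterol synthesis (gene 72999, mm10 chromosome 1), rose from 22.0 ± 4.51 to 49.2 ± 5.72 CPM (SD, log2 fold change 1.16 ± 0.12, adjusted p = 0.00025). Dio1, which converts thyroxine, rose from 9.65 ± 1.11 to 22.6 ± 2.48 CPM (1.23 ± 0.16, adjusted p = 0.0030). Falls were called for the thymidine phosphorylase Tymp (-0.84 ± 0.12, adjusted p = 0.0039) and the sulfide oxidase Ethe1 (-0.68 ± 0.09, adjusted p = 0.0039). Of the other genes with the largest changes each lost its call without at least 1 library.

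No list member among the peroxisomal, mitochondrial, omega-oxidation, ketogenesis or lipid handling genes was called in KO Wy, with camera adjusted p of 0.74, 0.18, 0.98, 0.051 and 0.15. Over each list alone 3 lipid handling genes rose and 2 fell and 1 ketogenesis gene fell. Among called lists were Kupffer markers (0 of 11 called, 2 higher over the list alone, median 0.34, -0.03 under library totals, adjusted p = 1.3e-05). So were sinusoidal endothelium (1 of 9 higher, median 0.25, -0.10 under library totals, adjusted p = 0.0013) and NRF2 genes (0 of 18 called, 6 lower and 1 higher over the list alone, median -0.13, adjusted p = 0.0058; 0.0689 without KO Wy 1). Each lost its call, at adjusted p = 0.61 with an estimated correlation, and the number of lists called was 6 without KO control 1, 5 without KO control 3 and 5 and 7 without KO Wy 2 and 3. In all 34 genes were called, 19 higher and 15 lower, and 1998 had an unadjusted p below 0.05. The count was 5 without KO control 1, 4 without KO control 2 and 10 without KO Wy 1. It was 18, 22, 19 and 21 without WT control 3, WT Wy 1, WT Wy 2 and WT fenofibrate 3, and 98, 105 and 157 without KO fenofibrate 1, 2 and 3. DESeq2 called 284, a filter at 5 CPM gave 58, no filter gave 73, the KO groups compared alone gave 67 and library totals gave 2980. The test against 1.5-fold in edgeR called 0 genes, beside the 1998 at an unadjusted p below 0.05 without that threshold and the 284 of DESeq2.

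Fenofibrate in KO gave a different picture. Cyp2c55 (gene 72082, mm10 chromosome 19) rose from 0.882 ± 0.0524 to 63.8 ± 12.1 CPM (SD, n = 3 each, log2 fold change 6.17 ± 0.23, SE, adjusted p = 9.6e-12). Cyp2b10, the classical target of CAR (gene 13088, mm10 chromosome 7), rose from 18.1 ± 11.5 to 229 ± 41.5 CPM (3.67 ± 0.39, adjusted p = 2.8e-05). It was also called higher with fenofibrate in WT, at 23.8 ± 7.57 against 11.4 ± 0.924 CPM, a call kept under 23 of 31 alternatives. In KO, Cyp2c29 rose from 1041 ± 137 to 3756 ± 108 CPM (1.85 ± 0.17, adjusted p = 6.0e-06) and Gstm3 from 71.8 ± 9.54 to 467 ± 177 CPM (2.70 ± 0.29, adjusted p = 2.8e-05). Close paralogs share sequence in these families, so the split among members is uncertain. The thiolase Acaa1b rose by 1.59 ± 0.10 (adjusted p = 3.0e-08) and the neutrophil gene S100a8 by 4.33 ± 0.62 (adjusted p = 0.0012). Cyp4a10 was called at 2.29 ± 0.40 (adjusted p = 0.0078) but not without KO control 2 (2.19, adjusted p = 0.058). Among falls, Hsd3b3 stood at -1.27 ± 0.19 (adjusted p = 0.0018, and 0.055 with only the compared groups fitted), and C9 at -0.80 ± 0.15 (adjusted p = 0.012) was lost without KO control 1 (adjusted p = 0.053) or 2 (0.058). Pdk4 (-0.34 ± 0.23, adjusted p = 0.53) was not called.

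Xenobiotic genes rose as a group with fenofibrate in KO, 13 of 19 higher and none lower, or 16 over the list alone (median 1.19, camera adjusted p = 8.4e-55), with Ces2a at 1.15 ± 0.10 (SE, n = 3 each). NRF2 genes rose in 8 of 18, or 10 over the list alone, and none fell (median 0.38, adjusted p = 5.3e-20), with Gstm1 at 1.19 ± 0.10 and Gstm4 at 1.86 ± 0.16. These 2 lists held with an estimated correlation and the remaining 8 did not, and without KO fenofibrate 2 the number of lists called was 16 instead of 10. Lipoprotein genes were lower in 4 of 16, or 8 over the list alone (median -0.30, adjusted p = 2.0e-08 and adjusted p = 0.065 with an estimated correlation). Higher was the cell cycle list (2 of 31, median 0.64, adjusted p = 5.1e-07 and adjusted p = 0.44 with an estimated correlation). So were omega oxidation (3 of 9 higher, 1 lower, median 0.52, adjusted p = 0.00094 and adjusted p = 0.23 with an estimated correlation) and female-biased genes (4 of 13, median 1.03, adjusted p = 0.00058 and adjusted p = 0.056 with an estimated correlation). Infiltrating myeloid markers were higher too (1 of 7, median 0.71, adjusted p = 0.00058 and adjusted p = 0.12 with an estimated correlation). Without KO fenofibrate 1, which stood apart in acute phase counts, their median was 0.33 (adjusted p = 0.015). The omega-oxidation median ran from 0.18 to 0.53 without single libraries, and its camera adjusted p reached 0.036 without KO fenofibrate 3. The female-biased list shares Cyp2b9 and Cyp2b13 with the xenobiotic list. Lower were male-biased genes (0 of 12 called, median -0.38, adjusted p = 0.0019 and adjusted p = 0.23 with an estimated correlation). So were glucose genes (1 of 23, median -0.16, adjusted p = 0.022 and adjusted p = 0.23 with an estimated correlation) and stress genes (0 of 16 called, median -0.14, adjusted p = 0.0497 and adjusted p = 0.5 with an estimated correlation; 0.0533 with RLE scaling). The glucose list was lost without KO fenofibrate 1 (adjusted p = 0.120). The stress list was lost without any WT control library, WT fenofibrate 1, KO control 1 or 2, KO Wy 2 or KO fenofibrate 3 (adjusted p up to 0.433, without KO fenofibrate 3, where the median was 0.05). Peroxisomal (2 of 26 higher, 1 lower, adjusted p = 0.21) and mitochondrial genes (1 of 20 higher, adjusted p = 0.5) were not called.

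In total 220 genes were called with fenofibrate in KO, 142 higher and 78 lower, and 2165 had an unadjusted p below 0.05. The number was 55, 54 and 105 without KO control 1, 2 and 3 and 482 without KO fenofibrate 2. DESeq2 called 523, the test against 1.5-fold 16, library totals 95, and the KO groups compared alone 33. By edgeR 4 genes were called the same way with both diets in KO and 1 in opposite directions. Independent responses would share 0.189 higher and 0.0822 lower, which leaves out the effect of the shared controls. The overlap was 0 without KO control 2, 1 without KO control 1, 2 without KO control 3, 1 and 8 without KO Wy 1 and 2, and 8, 20 and 11 without KO fenofibrate 1, 2 and 3. DESeq2 gave an overlap of 46. Correlation across genes was 0.461 against 0.487 for simulated unchanged groups with the same controls. The covariance was 0.0741 against 0.0434 ± 0.0020 (SD, 20 simulations). For genes of at least 1 CPM in KO control the covariance was 0.0242 against 0.0148 and r was 0.370 against 0.491. The covariance exceeded the simulated value and the correlation did not, so a shared response in KO is neither shown nor excluded.

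**Figure D3:**
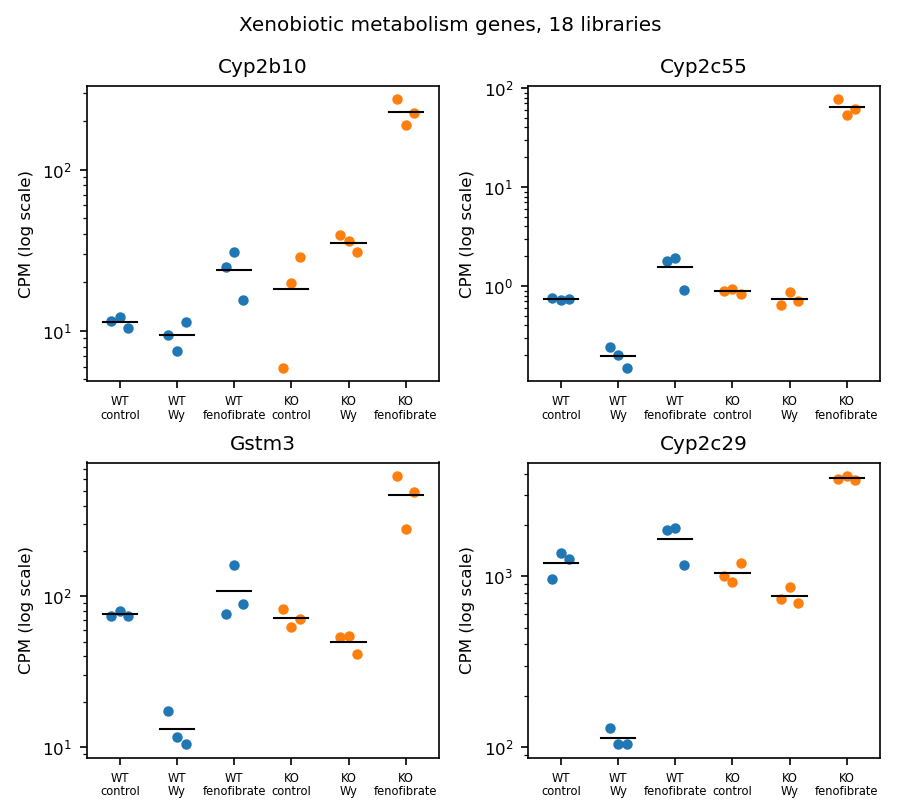
CPM on a log scale of Cyp2b10, Cyp2c55, Gstm3 and Cyp2c29 in 18 libraries of 6 groups, a point per library and a line at the group mean. Cyp2c55 rose from 0.882 to 63.8 CPM with fenofibrate in KO.

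The diets were also compared directly in KO, again at 0.1% against 0.5%. Lower with Wy than with fenofibrate were Cyp2c55 (-6.43 ± 0.23, SE, n = 3 each, adjusted p = 6.8e-12), Gstm3 (-3.22 ± 0.29, adjusted p = 2.4e-06), Cyp2b10 (-2.70 ± 0.37, adjusted p = 0.00054) and Acaa1b (-1.50 ± 0.10, adjusted p = 4.9e-08). Higher with Wy were Insig2 (1.38 ± 0.12, adjusted p = 1.6e-06), the clock repressor Cry1 (1.56 ± 0.19, adjusted p = 0.00011), the clock activator Arntl (2.47 ± 0.40, adjusted p = 0.0023) and the junction gene Cldn1 (1.52 ± 0.18, adjusted p = 9.5e-05). The circadian list as a whole was not among the 9 lists called. Xenobiotic genes were lower with Wy in 13 of 19, or 15 with 1 higher over the list alone (median -1.35, camera adjusted p = 5.9e-52). The same held for NRF2 genes in 9 of 18, or 11 (median -0.67, adjusted p = 4.5e-31), and female-biased genes in 4 of 13, or 6 (median -0.20, adjusted p = 0.00045). These 3 lists held with an estimated correlation. Cyp2b9 and Cyp2b13 are members of both the xenobiotic and the female-biased list, so these 2 calls are not independent. The female-biased median ran from -0.51 to -0.13 without single libraries. Lost with it, given with median and camera adjusted p, were omega oxidation (median -0.39, adjusted p = 0.0030 and adjusted p = 0.48 with an estimated correlation), lipoproteins (0.15, -0.26 under library totals, 0.0030 and adjusted p = 0.48 with an estimated correlation) and the cell cycle (-0.27, 0.0030 and adjusted p = 0.62 with an estimated correlation). Stress genes (0.26, -0.10 under library totals, 0.022 and adjusted p = 0.52 with an estimated correlation), Kupffer markers (0.23, -0.17 under library totals, 0.033 and adjusted p = 0.62 with an estimated correlation) and myeloid markers (-0.25, 0.039 and adjusted p = 0.48 with an estimated correlation) were lost as well. Under library totals the calls of lipoproteins (0.258), the cell cycle (0.0714), Kupffer (0.170) and myeloid markers (0.235) were also lost. Without KO fenofibrate 3 the calls of omega oxidation (adjusted p = 0.127), lipoproteins (0.0686), the cell cycle (0.0591), stress genes (0.287) and Kupffer markers (0.688) were lost. Without KO fenofibrate 1 those of lipoproteins (0.0511), the cell cycle (0.221) and myeloid markers (0.258) were lost. So were those of lipoproteins (0.0670), the cell cycle (0.0670), Kupffer (0.298) and myeloid markers (0.0670) without KO Wy 3, stress genes without KO Wy 1 (0.0636) or 2 (0.0598), and myeloid markers without KO Wy 1 (0.0993) or WT fenofibrate 2 (0.0502). In all 411 genes were called, 185 higher and 226 lower with Wy. The number was 206 and 254 without KO Wy 1 and 2 and 730 without KO fenofibrate 3, and DESeq2 called 743, the KO groups compared alone 47, the test against 1.5-fold 34 and library totals 4071.

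The basal effect of genotype was read from KO control against WT control. Fgf21 had 0 counts in KO control against 0.845 CPM in WT control, at least 85.5-fold lower. Cyp4a10 fell from 86.7 ± 25.1 to 1.00 ± 0.643 CPM (SD, n = 3 each, log2 fold change -6.42 ± 0.45, SE, adjusted p = 1.7e-08). Lower in KO were also Vnn1 (-5.95 ± 0.31, adjusted p = 4.3e-10), the lipid droplet gene Fitm1 (-4.58 ± 0.23, adjusted p = 2.8e-10) and the carnitine carrier Slc25a20 (-2.02 ± 0.08, adjusted p = 1.7e-11). Higher in KO were the inflammasome gene Nlrp12, from 0.182 ± 0.0491 to 11.4 ± 0.147 CPM (5.94 ± 0.20, adjusted p = 1.2e-12), the water channel Aqp4 (6.29 ± 0.32), the protease inhibitor Serpine2 (5.05 ± 0.26) and the IGF carrier Igfbp1 (2.59 ± 0.48, adjusted p = 0.0011). Edv, an endogenous viral locus with related copies in the genome and thus an uncertain count, was higher by 8.20 ± 0.56. Pdk4 was higher in KO, by 1.81 ± 0.25 (adjusted p = 7.5e-05).

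Oxidation lists were lower in KO control than in WT control. Peroxisomal genes were lower in 14 of 26 and higher in 1, or 19 and 4 over the list alone (median -0.50, camera adjusted p = 9.9e-26), with Pxmp4 at -1.81 ± 0.10 (SE, n = 3 each). Mitochondrial genes were lower in 16 of 20 (median -0.60, adjusted p = 1.8e-34), with Cpt2 at -1.39 ± 0.09, and omega-oxidation genes in 8 of 9 with 1 higher (median -1.67, adjusted p = 3.3e-33). Lipid handling genes were lower in 14 of 24 and higher in 1, or 16 and 1 over the list alone (median -0.65, adjusted p = 1.2e-18), with Plin5 at -3.39 ± 0.25. These 4 lists held with an estimated correlation and the other 8 did not. Lower were ketogenesis (3 of 4, adjusted p = 0.0015 and adjusted p = 0.24 with an estimated correlation) and cholesterol synthesis (1 of 24, adjusted p = 0.0065 and adjusted p = 0.66 with an estimated correlation). So were hepatokines (5 of 15, 2 higher, median -0.10, 0.23 under library totals, adjusted p = 0.0065 and adjusted p = 0.33 with an estimated correlation). Lower too were bile acid genes (8 of 22, 1 higher, median -0.24, 0.09 under library totals, adjusted p = 0.013 and adjusted p = 0.33 with an estimated correlation, 0.123 under library totals). NRF2 genes were lower as well (7 of 18, 1 higher, median -0.26, 0.05 under library totals, adjusted p = 0.0072 and adjusted p = 0.42 with an estimated correlation, 0.0898 under library totals). Higher were stress genes (6 of 16, median 0.51, adjusted p = 0.00028 and adjusted p = 0.2 with an estimated correlation). So were xenobiotic genes (4 of 19, adjusted p = 0.013 and adjusted p = 0.5 with an estimated correlation), such as Cyp2c37 (1.54 ± 0.18), and pericentral genes (3 of 9, adjusted p = 0.0047 and adjusted p = 0.089 with an estimated correlation). Calls were lost for cholesterol synthesis without WT control 2 (adjusted p = 0.0526), for bile acids without WT control 2 (0.0504) or KO control 1 (0.0501), and for xenobiotic genes without WT control 1 (0.0501) or KO control 2 (0.0822).

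In all 1416 genes differed between the genotypes on control diet, 610 higher and 806 lower in KO, while 813 passed an adjusted p of 0.01, 351 the test against 1.5-fold and 2731 library totals. Of the 806 lower genes 437 rose and 144 fell with Wy in WT, and of the 610 higher genes 226 fell and 94 rose, where 2875 of all 14241 tested genes rose and 2708 fell. Both comparisons used the same 3 WT control libraries, so the genotype effects were also handed to other genes of like abundance in 20 simulations on shared controls. Of the simulated lower genes 20.1% rose and 18.4% fell on average, against 54.2% and 17.9% observed. Of the simulated higher genes 14.9% fell and 20% rose, against 37.0% and 15.4% observed. The mice were of a mixed background and how the genotypes were bred is not given in the sources used here, so genes linked to strain rather than to the receptor are not set apart.

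Whether the response depended on genotype was tested as an interaction, the KO response minus the WT response. For Wy 4001 genes were called, 1994 positive and 2007 negative, and for fenofibrate 3178, 1523 positive and 1655 negative. Ehhadh gave -6.58 ± 0.19 for Wy (SE, n = 3 per group, adjusted p = 7.2e-14) and -6.35 ± 0.18 for fenofibrate (adjusted p = 1.1e-13). Pdk4 gave -7.36 ± 0.36 and -8.20 ± 0.36, and Slc27a1 -5.86 ± 0.22 and -5.54 ± 0.22. In the other direction Cyp2c50 gave 5.42 ± 0.25 and 4.23 ± 0.24, Gls2 2.69 ± 0.15 and 2.36 ± 0.15, and Ass1 2.33 ± 0.16 and 2.05 ± 0.16. Cyp2b10 gave 2.60 ± 0.51 for fenofibrate (adjusted p = 0.00099) and Cyp2c55 5.12 ± 0.31 (adjusted p = 1.4e-09).

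Of the 5583 genes called with Wy in WT 3574 (64.0%) had a called interaction. Of the 5583, 24 were also called the same way in KO, where independent calls would share 6.69, and 3 the opposite way. For the 1743 that changed at least 2-fold, 1305 (74.9%) had a called interaction, and the median absolute change of 1.59 in WT stood against a median of 0.06 in KO, signed by the WT direction. Of the 5253 genes called with fenofibrate 2913 (55.5%) had a called interaction. Of the 5253, 121 were called the same way in KO, where independent calls would share 41.1, and 28 the opposite way. In KO only, 71 genes were called. Among the 1603 with at least 2-fold change 1136 (70.9%) had a called interaction, with a median of 1.56 in WT and 0.15 in KO. These genes were chosen by their change in WT, which raises the WT medians and not those in KO. The WT libraries used for the choice also enter the interaction, so the shares with a called interaction can be raised as well.

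Lists were tested for the interactions as well. For Wy the responses of peroxisomal (3 positive and 19 negative of 26, median -1.56, camera adjusted p = 3.5e-44), mitochondrial (19 negative of 20, adjusted p = 1.0e-50) and omega-oxidation genes (8 negative and 1 positive of 9, adjusted p = 6.3e-12) were smaller in KO. So were those of ketogenesis (4 negative of 4, adjusted p = 2.4e-07) and lipid handling genes (20 negative of 24, adjusted p = 8.2e-46). Responses were more positive in KO for xenobiotic (9 of 19 positive, 3 negative, median 1.24, adjusted p = 2.3e-10) and periportal genes (7 of 8, median 1.67, adjusted p = 6.6e-11). They were also more positive for amino acid (13 of 20, median 0.63, -0.55 under library totals, adjusted p = 4.8e-11) and pericentral genes (4 of 9, 1 negative, median 0.80, -0.31 under library totals, adjusted p = 0.00027). These 9 lists held with an estimated correlation. For fenofibrate the lists that held were peroxisomal (20 negative and 2 positive, adjusted p = 2.3e-47), mitochondrial (18 negative; 1.5e-48), omega-oxidation (7 negative and 1 positive; 1.9e-09) and lipid handling genes (20 negative; 2.2e-49). Xenobiotic (12 positive and 2 negative, median 2.10, adjusted p = 1.9e-15) and periportal genes (6 positive, median 1.07; 5.0e-08) held as well. So did amino acid (15 positive, median 0.67, -0.10 under library totals, adjusted p = 6.3e-13) and pericentral genes (4 positive, median 0.32, -0.43 under library totals; 0.00034).

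The other interaction lists were lost with an estimated correlation, and the first p given for each is the camera adjusted p. For Wy these were lipogenesis (adjusted p = 0.0032 and adjusted p = 0.39 with an estimated correlation), bile acids (0.0001 and adjusted p = 0.06 with an estimated correlation). Others were acute phase (1.7e-05 and adjusted p = 0.35 with an estimated correlation), cell cycle (0.0032 and adjusted p = 0.52 with an estimated correlation) and circadian genes (0.035 and adjusted p = 0.44 with an estimated correlation). Male-biased genes (0.015 and adjusted p = 0.33 with an estimated correlation) and Kupffer markers (3.3e-06 and adjusted p = 0.21 with an estimated correlation) followed. The medians for bile acids (0.40 to -0.73), acute phase (1.15 to -0.01), circadian (0.42 to -0.74), male-biased (0.98 to -0.17) and Kupffer genes (1.02 to -0.14) turned under library totals, and the calls of lipogenesis (0.0640), cell cycle (0.0813) and circadian genes (0.0555) were lost there. The circadian call was also lost without WT control 2 (0.0587) or KO Wy 1 (0.050006). For fenofibrate they were ketogenesis (1.4e-05 and adjusted p = 0.061 with an estimated correlation), lipogenesis (0.011 and adjusted p = 0.4 with an estimated correlation), bile acids (0.00011 and adjusted p = 0.063 with an estimated correlation). Others were acute phase (4.9e-08 and adjusted p = 0.25 with an estimated correlation) and NRF2 genes (0.031 and adjusted p = 0.4 with an estimated correlation). Hepatokines (0.028 and adjusted p = 0.37 with an estimated correlation) and circadian genes (0.028 and adjusted p = 0.4 with an estimated correlation) were lost as well. Male-biased (0.011 and adjusted p = 0.28 with an estimated correlation), Kupffer (0.00021 and adjusted p = 0.31 with an estimated correlation) and female-biased genes (0.026 and adjusted p = 0.15 with an estimated correlation, median 1.07, mean 0.07 and test direction down) completed the set. Under library totals the medians of bile acids (-0.24), NRF2 (-0.54), hepatokines (-0.30), circadian (-0.27) and Kupffer genes (-0.03) turned, and the calls of lipogenesis (0.0614), NRF2 (0.239), hepatokines (0.132), circadian (0.0545) and female-biased genes (0.811) were lost. Without KO fenofibrate 1, which alone held very high Saa counts, the acute phase median went from 1.51 to 1.03 (adjusted p = 2.9e-07). Calls were lost for NRF2 genes without WT fenofibrate 3 (0.0626) or KO fenofibrate 1 (0.0915), lipogenesis without KO fenofibrate 2 (0.0742) and hepatokines without KO control 1 (0.0553) or KO fenofibrate 2 (0.163). They were also lost for circadian genes without WT control 2 (0.0513), WT fenofibrate 1 (0.0714) or KO fenofibrate 3 (0.0862), and for female-biased genes without WT fenofibrate 1 (0.0711). Library totals called 10063 genes for Wy, 9860 of them negative, and 7432 for fenofibrate, 7166 of them negative, and the test against 1.5-fold called 1153 and 871.

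**Figure D4:**
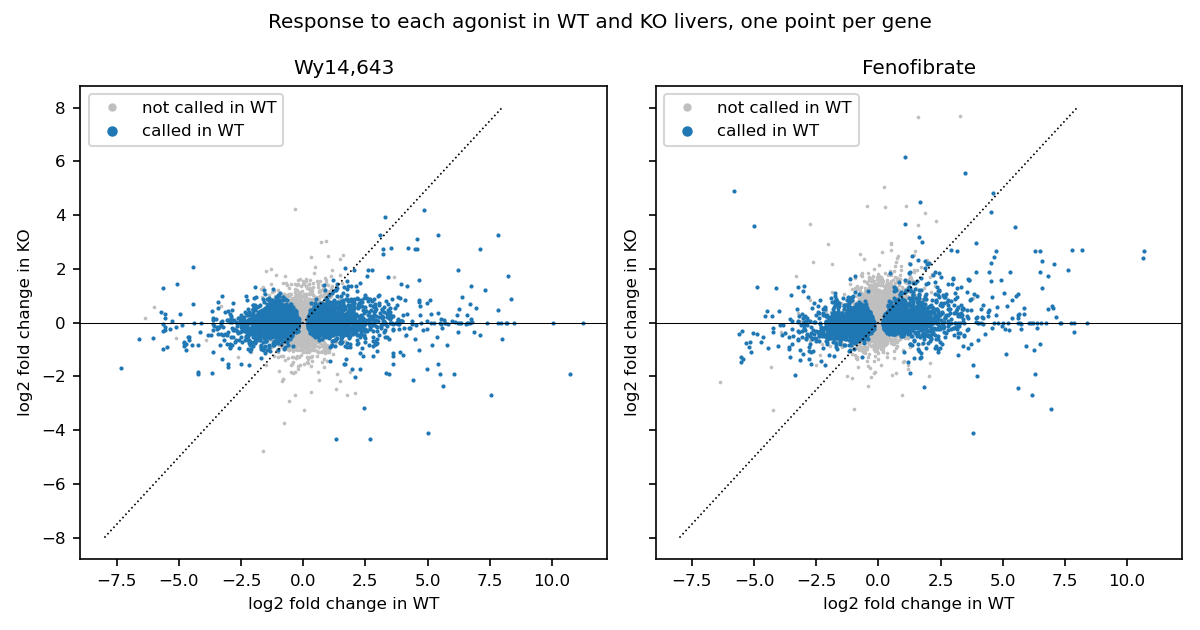
Log2 fold change in KO against that in WT for Wy and for fenofibrate, a point per gene, in blue if called in WT, with a dotted line of equal change. Genes changed at least 2-fold by Wy in WT had a median absolute change of 1.59 there. Their median in KO, signed by the WT direction, was 0.06. The choice by the WT change raises the first value.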

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

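For these results, the breakdown of the interaction splits, the test on 13 xenobiotic genes, the share of calls kept without each library and the count of genes that differ from any common shift were chosen after the result was seen, and the other tests before.

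Responses that differed between the genotypes by the interaction test were the first reason for a closer look. For Wy 4001 genes differed. Positive values mean a KO response above the WT response, which a fall in WT alone can give. They were 6.94 for Saa2, 6.58 for Edv, 6.51 for Saa1, 5.98 for Orm3 and 5.91 for Cyp2c70. Saa1 and Cyp2c70 fell with Wy in WT. Negative values were -7.49 for Fbp2, -7.36 for Pdk4, -7.23 for Cyp4a14, -6.74 for Acot2, -6.61 for Acot5, -6.58 for Ehhadh, -6.04 for Cyp4a10, -5.90 for Acot1, -5.06 for Gm15441 and -4.82 for Vnn1. Smaller ones were -4.08 for Cd36, -3.87 for Cpt1b, -3.03 for Ucp2, -2.99 for Plin2, -2.61 for Pex11a, -2.45 for Fabp1, -2.29 for Scd1, -0.99 for Ccnd1, -0.73 for Cpt1a and -0.64 for Creb3l3. Some calls depended on single libraries. Edv stood at 0.59 without WT control 2, and its call was also lost, at 6.47 to 6.68, without any WT Wy, KO control or KO Wy library, WT fenofibrate 2 or KO fenofibrate 2. Fbp2 was lost without WT control 2 (-7.39) or KO control 1 (-5.60). Ccnd1 was lost without any WT control library, WT Wy 1 or 2, KO control 1 or 3, or KO Wy 2 or 3 (-1.07 to -0.80), and kept its call under 17 of 31 alternatives.

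For fenofibrate 3178 genes differed between the genotypes. Positive values were 10.71 for Saa2, 8.60 for Saa1, 6.42 for Saa3, 5.12 for Cyp2c55, 4.91 for Apol9a and 2.60 for Cyp2b10. Negative values were -8.20 for Pdk4, -7.28 for Acot5, -6.97 for Cyp4a30b, -6.58 for Acot2, -6.47 for Cyp4a14, -6.35 for Ehhadh, -5.34 for Gm15441, -5.30 for Acot1, -4.29 for Cyp4a10 and -3.98 for Cd36. Smaller ones were -3.43 for Plin2, -3.38 for Vnn1, -3.27 for Cpt1b, -2.96 for Ucp2, -2.51 for Pex11a, -1.78 for Fabp1, -1.26 for Ccnd1, -0.79 for Cpt1a, -0.64 for Cyp8b1 and -0.55 for Creb3l3. The Saa values rested in large part on KO fenofibrate 1, and without it they were 5.52 for Saa2, 4.42 for Saa1 and 3.22 for Saa3, all still called. The call of Cyp8b1 was lost without WT control 3 (-0.56), KO control 3 (-0.54) or KO fenofibrate 3 (-0.53).

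A signal also appeared in loci with no gene identifier, which entered the comparisons only in the alternative with all loci. Of 1266 such loci tested, 249 were higher and 96 lower with Wy in WT and 218 higher and 82 lower with fenofibrate in WT.

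The interactions were weighed first. Of the calls of at least 2-fold, 50.8% of 1581 (95% interval 48.3 to 53.3) for Wy and 52.8% of 1277 (49.999 to 55.5) for fenofibrate stayed at that size under any common shift. TMM centres the values and so balances rises and falls, so these shares decide nothing on a scaling error from the Mup loci. Such an error moves all genes by 1 amount, and if it alone made the calls, few genes would differ from some common shift. At every shift from -4 to 4 at least 3980 genes for Wy and 3176 for fenofibrate differed from it. These were 99.5% (96.9 to 102.1) and 99.9% (96.9 to 103.0) of the 4001 and 3178 called. TMM had already centred the values, and the fewest genes differed at small shifts of 0.04 for Wy and -0.02 for fenofibrate. A number near that of the calls therefore follows from the centring. No common shift removed the calls, but this does not test a scaling error further. Whether such an error moved single genes across the threshold stays open. At least as many genes were called in 4 of 31 splits of the libraries for Wy, the real one included (4001 against a highest other of 5192) and 6 of 31 for fenofibrate (3178 against 4409). The splits with more calls were among the 5 that kept the treated libraries of the genotypes apart, which gave 3920 to 5192 and 3271 to 4409. These still carry the difference between the genotypes, and the other 25, with at most 4 and 25 calls, put treated libraries of both genotypes in a group. The splits alone therefore do not settle whether chance can be excluded, and the calls rest on the fitted spread. The pattern is not called biological here, as a candidate explanation by loss of PPARA was not separated from the other differences between the genotypes.

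Genes that rose with fenofibrate in KO were weighed next. PPARA activity left in the null livers would make most of them rise with Wy in WT too, and 15.4% of 13 xenobiotic genes (95% interval 1.92 to 45.4) and 27.9% of 129 others (20.4 to 36.5) did, where 20.2% of all tested genes rose. The test on the 13 was chosen after the result was seen, and their list had a median of -0.86 with Wy in WT, so their share decides nothing. For the 129 others the share argues against such activity as the cause of most rises, if it acts as Wy does in WT. That condition was not tested, and the diets differed in WT (xenobiotic list, camera adjusted p = 4.3e-48). Of the 220 genes called in KO, 121 were called the same way with fenofibrate in WT and 28 the opposite way. The effect of fenofibrate itself through PPARA was not set apart, and whether such activity adds to a part of the others stays open. All fenofibrate libraries lay above all controls for 96.5% of the 142 genes, but a call in 3 against 3 libraries nearly requires this, so the share decides nothing. If 1 library made all 220 calls, under 10% of them would stay without it. The lowest share still called was 24.1% (95% interval 18.6 to 30.3), without KO control 1, so no single library makes all of the calls. It was 24.5% and 44.1% without KO control 2 and 3 and 61.4%, 90.9% and 53.2% without KO fenofibrate 1, 2 and 3. How far single control libraries add to the calls stays open. The real grouping called 220 and the highest other split 1, in 1 of 10 splits, which are too few for a share under 0.05. An effect of fenofibrate through other receptors is a candidate explanation that no value here tests, and the pattern is not called biological.

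The difference between the genotypes on control diet was weighed last. Within 10 Mb of Ppara lay 1.98% of the 1416 called genes, but the 250 tested genes there make up at most 17.7% of them, so this share does not test whether a longer strain segment holds most of the calls. Whether a segment of that size added calls stayed open, with 28 of 250 genes called there (11.2%) against 9.92% elsewhere (odds ratio 1.15, 95% interval 0.741 to 1.71, Fisher exact p = 0.521). The real grouping called 1416 and the highest other split 0, in 1 of 10 splits. Strain differences elsewhere in the genome remain a candidate explanation that was not tested.

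For the other comparisons the real grouping also stood first in 1 of 10 splits, which are too few for a share under 0.05. Wy in WT gave 5583 against a highest other of 1, fenofibrate in WT 5253 against 0, Wy in KO 34 against 1, the direct comparison in WT 128 against 0 and that in KO 411 against 212.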

How the results depend on the processing

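Robust dispersion, the Mup loci left out, all loci, lists without each library and list medians under other scalings were chosen after the result was seen, and the other alternatives before. Counts of calls depended on the libraries used and on the threshold. A stricter threshold or an added fold requirement lowered counts by construction, and for every other value below the cause was not tested. All alternatives of the fit, filter, scaling, threshold and libraries were run for the counts of called genes. Overlaps were recounted only under the stricter threshold, the block, DESeq2 and single libraries of the same genotype left out. List calls were recomputed under some of the alternatives only. Of 354 pairs of a named gene and a comparison in which it was called, 238 kept the call under every alternative, 116 lost it under at least 1, and 7 turned direction under library totals.

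An adjusted p of 0.01 left 5 genes for Wy in KO, 53 for fenofibrate in KO, 813 between genotypes, 2369 and 1878 interactions, 41 and 132 between diets in WT and KO, and 1 in the KO overlap. The test against 1.5-fold left 1707 and 1532 in WT, 0 and 16 in KO, 351 between genotypes, 1153 and 871 interactions, and 18 and 34 between diets. Library totals gave 10156 (9700 higher, 456 lower) and 10396 (10002, 394) in WT, 2980 (24, 2956) and 95 (86, 9) in KO, 2731 (2431, 300) between genotypes, 10063 (203, 9860) and 7432 (266, 7166) interactions, and 47 (14, 33) and 4071 (26, 4045) between diets. They also turned Apoa1 with Wy in WT to 0.45, Csf1r to 0.13 with Wy and 0.27 with fenofibrate in WT, the value for Clec4f, WT fenofibrate against WT control, to 0.0550, those for Csf1r, genotype by Wy interaction, to -0.0691 and Clec4f, genotype by Wy interaction, to -0.0659, and the fenofibrate interaction of Csf1r to -0.17.

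No filter gave 73 for Wy in KO, and the filter of 5 CPM, with 6409 genes tested, gave 3439 and 3319 in WT and 58 for Wy in KO. The compared groups alone gave 67 and 33 in KO and 47 between diets in KO. DESeq2 gave 284 and 523 in KO, 303 and 743 between diets and 46 in the KO overlap, and RLE gave 40 for Wy in KO (18 higher, 22 lower). Lists called with an estimated correlation were 9, 8, 0, 2, 4, 9, 8, 5 and 3, against 17, 18, 3, 10, 12, 16, 18, 12 and 9, in the order WT, KO, genotype, interactions and diets. Fry called 27 with Wy in WT, 0 and 5 in KO, 25 for the Wy interaction and 3 between diets in KO.

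Without single libraries counts were 4625 to 6055 for Wy and 4389 to 5680 for fenofibrate in WT, 4 to 157 and 54 to 482 in KO, 979 to 1713 between genotypes, 3274 to 4545 and 2638 to 3299 for interactions, and 40 to 203 and 206 to 730 between diets. Overlaps, for which only libraries of the same genotype were left out, were 3584 to 4116 in WT and 0 to 20 in KO. Lists called were 16 to 19, 15 to 19, 2 to 7, 9 to 16, 10 to 13, 15 to 18, 16 to 18, 11 to 15 and 6 to 12.

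A block on the library number gave 5540, 5183, 38, 201, 1373, 3874, 3082, 109 and 372 calls. Of 45 pairs of libraries with the same number in different groups 7 correlated above 0.1 after group means were removed (r from -0.223 to 0.193), and 8 libraries had their best partner among their own number, so the numbers were not treated as pairs.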

Other observations

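The examples of this part were picked after the result was seen, and no test beyond those of the report was added. Among genes not described so far, the aquaglyceroporin Aqp3 rose by 8.01 ± 0.41 with Wy in WT (SE, n = 3 each, adjusted p = 2.4e-11 by edgeR), the zinc transporter Slc39a5 by 6.60 ± 0.25 and the uncoupling protein Ucp2 by 3.36 ± 0.15. The apolipoprotein L genes Apol9a and Apol9b fell with Wy in WT (-5.57 ± 0.27 and -5.29 ± 0.21) and with fenofibrate (-4.48 ± 0.25 and -4.55 ± 0.20). These are close paralogs, so the split between them is uncertain.

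Livers of KO mice on control diet differed in genes outside fatty acid oxidation. The growth arrest transcript Gas5 was higher by 2.62 ± 0.18 (SE, n = 3 each, adjusted p = 1.6e-08 by edgeR), the oxysterol hydroxylase Cyp39a1 by 2.32 ± 0.27, the methyltransferase Nnmt by 2.45 ± 0.45, the transporter Slco1a4 by 1.71 ± 0.14 and the carboxylase Acacb by 1.77 ± 0.21. The lysolipid transporter Mfsd2a (-4.12 ± 0.38), the malic enzyme Me1 (-1.60 ± 0.16) and E2f8 (-2.19 ± 0.16) were lower.

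A single library, KO fenofibrate 1, held high acute phase counts. Saa1 stood at 624 CPM there against 12.9 and 10.9 in the other libraries of its group, Saa2 at 531 against 5.03 and 4.82, Saa3 at 57.3 against 2.74 and 1.75, and Lcn2 at 101.4 against 2.24 and 1.80. Xist, the transcript of the inactive X chromosome, stood at 2.69 CPM in WT Wy 3 and at no more than 0.0109 in the other 17 libraries, while the Y gene Ddx3y was between 12.7 and 16.8 CPM in all 18.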
